A study of Mus musculus with 4 samples.

How the data were processed

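Total RNA was the starting material, per the labels. Per the labels' protocols, sorted cells were lysed in Trizol LS and libraries were made with SMARTer amplification, which copies small amounts of RNA by PCR. The deposited values are raw read counts per Ensembl gene, 1 file per library, with replicates not pooled. Per the submitters' processing notes, STAR, Picard, HTSeq and DESeq2 were used with the mouse build mm9; their versions, order and annotation release are not given in the sources used here. HTSeq assigns a read to a gene and sets aside reads with several alignments or several genes, so genes with near-identical copies, such as ribosomal proteins with pseudogenes, are undercounted. Whether strand was used in counting is not given, so overlapping antisense genes cannot be told apart.

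The files held 45232 gene rows, of which 44585 matched a symbol. Symbols and transcript lengths came from GENCODE M21, which is on a later build than mm9, so no coordinates are printed. Rows that name no gene, which are HTSeq's uncounted classes and pasted totals, were kept out of library sizes and tests. Reads with no feature made up 13.8% of all reads in Scr 1, 11.4% in Scr 2, 8.31% in miR-99 KD 1 and 11.8% in miR-99 KD 2. Reads with several alignments made up 21.0%, 18.0%, 21.9% and 21.1%. Gene counts per library ran from 27295197 to 32350590. Mitochondrial genes took 0.990%, 0.357%, 0.729% and 1.00% of gene counts in the same order of libraries. Without molecular identifiers, any PCR copies that were not removed before counting are counted too.

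Libraries were grouped by the labels, 2 in Scr and 2 in miR-99 KD, from 2 mice in each group. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on genes kept by filterByExpr, with TMM scaling and Benjamini-Hochberg adjustment at 0.05, without a replicate block. Standard errors of log2 differences come from that fit, and CPM values use TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, over 28 lists fixed before the data were examined. Beside it stood camera with an estimated correlation and fry. None of the lists passed with an estimated correlation, where the lowest adjusted p was 0.732, or by fry, where it was 0.189. The median and the test differed in sign for 3 lists.

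The alternatives were fixed before the data were examined. They were DESeq2 1.42.0, limma-voom, glmTreat at a log2 difference of 0.5, 3 other scalings, no filter and a filter at 10 CPM in 2 libraries. Further ones were leaving out mitochondrial, ribosomal protein and globin genes, a replicate block, a threshold of 0.10 and leaving out each library. DESeq2 left the adjusted p of 2377 genes without a value, and these are not counted as lost.

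Genes were named by a rule fixed before the data were examined. It takes up to 12 genes in each direction with the smallest p among those that pass edgeR with groups that do not overlap, filled to 6 by p where fewer pass. It adds up to 4 genes of each list with the smallest p, and the published targets, sort markers and miR-99 host transcripts. The text names a part of the genes it takes, and a result it asks for is not reported here. Other genes named are said to have been chosen after their values were seen.

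The tests were tried on 10 sets of simulated counts with 200 of 15320 genes changed. edgeR recovered 22.6% of the 2-fold and 85.1% of the 4-fold changes with 10.4% of its calls false, and DESeq2 52.6% and 95.3% with 30.2% false. A stem cell list lowered by 0.7 on the log2 scale was called by camera in 10 of 10 sets. Simulated genes varied independently, so this does not test the preset correlation. Each gene also had the same spread in both simulated groups, with no shift shared by many genes of a library. The shares recovered may therefore not hold for the real libraries, in which edgeR called 0 genes. Seed sites were searched in 3′ untranslated regions of at least 50 bases, with shuffled sites kept where at least 20 genes held them.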

Results

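RNA was measured in GFP-positive LSK cells, the lineage-negative, Kit-positive, Sca-1-positive fraction of blood-forming tissue that holds mouse stem cells and their earliest progeny. The cells were sorted 3 months after transplantation of long-term haematopoietic stem cells. The transplanted cells carried either a scrambled control (Scr) or a knockdown of the microRNA miR-99 (miR-99 KD). Each group had 2 mice and 2 libraries. The gene counts per library were 32350590 in Scr 1, 28422748 in Scr 2, 27295197 in miR-99 KD 1 and 27314881 in miR-99 KD 2. The number of genes with at least 1 count was 23052 in Scr 1, 19717 in Scr 2, 19239 in miR-99 KD 1 and 19060 in miR-99 KD 2. The only comparison of the design asks how RNA levels in engrafted LSK cells differ with the knockdown.

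The mature microRNA is not measured by these libraries, so the knockdown itself could not be checked. The gene rows of Mir99a, Mir99b and Mir100 held 0 counts in all 4 libraries. Mir99ahg (ENSMUSG00000090386), the host transcript of miR-99a, had 397 and 411 counts in the Scr libraries and 132 and 195 in the miR-99 KD libraries. Its log2 difference was -1.07 ± 0.31 (SE, n = 2 per group), with an edgeR quasi-likelihood adjusted p of 0.248. Spaca6 (ENSMUSG00000080316), the host gene of miR-99b, had 16 and 13 counts in the Scr libraries and 5 and 9 in the miR-99 KD libraries, with an edgeR adjusted p of 0.677.

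Of 32 stem cell genes, 18 were lower in both miR-99 KD libraries than in both Scr libraries, 2 were higher and 12 overlapped. Of 24 erythroid-megakaryocytic genes, 12 were higher, 2 lower and 10 overlapped. Both lists passed camera with a preset correlation, and both calls were lost with an estimated correlation, at an adjusted p of 0.732. The adjustment gave this same value to many lists whose unadjusted p differed. By camera with an estimated correlation the unadjusted p was 0.325 for the stem cell list and 0.109 for the erythroid list. With n = 2 per group these correlations are themselves poorly known. Hlf (ENSMUSG00000003949), a transcription factor of stem cells, stood at 175 ± 3.6 CPM (normalised read counts scaled to the same library total, mean ± SD, n = 2) in Scr and 52.6 ± 2.8 in miR-99 KD. Mecom (ENSMUSG00000027684), another stem cell transcription factor, stood at 80.3 ± 4.7 and 17.0 ± 4.6 CPM. Tfrc (ENSMUSG00000022797), the transferrin receptor that takes up iron, stood at 435 ± 5.8 CPM in Scr and 944 ± 107 in miR-99 KD. Cldn13 (ENSMUSG00000008843), a claudin of erythroid cells, stood at 97.0 ± 1.2 and 185 ± 1.7 CPM. None of these genes passed the main test, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each passed DESeq2.

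Of 15320 genes tested, edgeR called 0 at an adjusted p of 0.05, and the lowest adjusted p was 0.191. At an unadjusted p under 0.05 it counted 2390 genes, 915 higher and 1475 lower in miR-99 KD, where chance alone gives 766. The share of these that was lower was 61.7%, and 79.1% when libraries were scaled by their totals alone. DESeq2 called 887 genes, 254 higher and 633 lower. Both miR-99 KD libraries lay outside the range of the Scr libraries on the same side in 7733 genes, or 50.5%, where chance gives 33.3%. The log2 CPM of the Scr libraries correlated at 0.972 (Pearson), and that of the miR-99 KD libraries at 0.944. Pairs across the groups correlated at 0.947 to 0.956. These counts moved with the library left out. A fit without a Scr library takes its spread from the miR-99 KD pair, and one without a miR-99 KD library from the Scr pair. edgeR called 1013 genes without miR-99 KD 1 and 437 without miR-99 KD 2, and its count at an unadjusted p under 0.05 was 1143 without Scr 1, 783 without Scr 2 and 4342 without miR-99 KD 1. DESeq2 called 131 without Scr 1, 27 without Scr 2 and 1506 without miR-99 KD 1. In simulated libraries of this size, with 200 genes and the stem cell list changed, 30.2% of DESeq2's calls were false. That share depends on how many genes change, so it does not carry over to the 887.

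The genes with the smallest edgeR p in each direction did not pass its threshold and are named as such. The 6 lower ones were Hlf, Dusp4, Adgrl4, Rab37, Spns2 and Gcnt2. Dusp4, a phosphatase that acts on MAP kinases, was 15.8 ± 2.9 CPM in Scr and 1.23 ± 0.074 in miR-99 KD, a log2 difference of -3.68 ± 0.31 (SE, n = 2 per group). Adgrl4, an adhesion receptor, was 706 ± 106 and 202 ± 4.6 CPM. Spns2, an exporter of sphingosine-1-phosphate, was 334 ± 11 and 139 ± 0.65 CPM. The 6 higher ones were Banp, Tfrc, Paqr9, Cldn13, Gfi1b and Dynll1. Gfi1b, a repressor needed for red cell and platelet formation, was 224 ± 1.5 CPM in Scr and 456 ± 66 in miR-99 KD. Dynll1, a dynein light chain, was 154 ± 3.0 and 375 ± 86 CPM. The edgeR adjusted p of these 12 genes was 0.191 to 0.197.

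**Figure D1:**
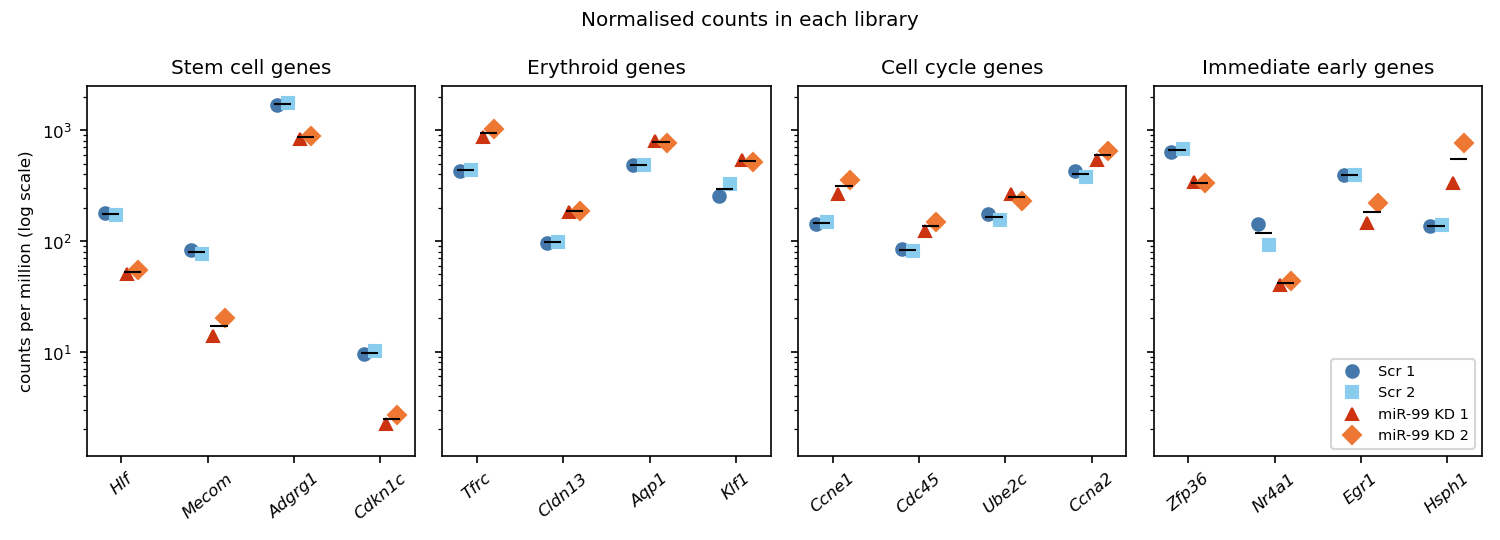
Normalised read counts (CPM) on a log scale in each of the 4 libraries for 16 genes, with black lines at the group means of 2 libraries. Hlf stands at 175 CPM in Scr and 52.6 in miR-99 KD, and Tfrc at 435 and 944.

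The stem cell list, fixed before the data were examined, fell in miR-99 KD by camera. Its 32 genes had a median log2 difference of -0.71, with an adjusted p of 3.5e-04, and with an adjusted p of 0.732 with an estimated correlation. DESeq2 called 11 of the 32, each lower. Adjusted over the list alone, edgeR called 11 lower and 1 higher, against 0 over all genes tested. The lower ones included Adgrg1, an adhesion receptor of stem cells, at 1738 ± 45 CPM in Scr and 863 ± 40 in miR-99 KD. Cdkn1c, the cell cycle inhibitor p57, stood at 9.79 ± 0.48 and 2.45 ± 0.31 CPM. The gene called higher was Clca3a1, named after its values were seen. The camera call was lost without Scr 1, with a median of -0.44 and an adjusted p of 0.167, and DESeq2 called 3 genes of the list without Scr 1 and 3 without Scr 2.

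Of the sort markers, Kit was called lower by DESeq2 and Ly6a by neither test. Kit stood at 1214 ± 93 CPM in Scr and 722 ± 73 in miR-99 KD, a log2 difference of -0.75 ± 0.15 (SE, n = 2 per group) with a DESeq2 adjusted p of 2.9e-04 and an edgeR adjusted p of 0.213. Ly6a, which encodes Sca-1, stood at 34.7 ± 17 and 17.3 ± 7.0 CPM, with nearly equal values in Scr 2, at 22.8, and miR-99 KD 2, at 22.3. Ly6a ranked between 5462 and 8986 among genes by CPM in the 4 libraries, whereas Car2, a carbonic anhydrase of erythroid cells chosen after its values were seen, ranked 1 or 3.

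The erythroid-megakaryocytic list rose in miR-99 KD by camera. Its 24 genes had a median log2 difference of 0.41 with an adjusted p of 0.0010, and an adjusted p of 0.732 with an estimated correlation. DESeq2 called 7 of them higher and 1 lower, the latter Itga2b, an integrin of platelet precursors named after its values were seen. Adjusted over the list alone, edgeR called 7 higher and 0 lower. Aqp1, a water channel of red cells, stood at 484 ± 4.9 CPM in Scr and 790 ± 23 in miR-99 KD. Klf1, a transcription factor of red cells, stood at 292 ± 54 and 530 ± 19 CPM. Globin genes took 0.324% of gene counts in Scr 1, 0.0814% in Scr 2, 0.354% in miR-99 KD 1 and 0.105% in miR-99 KD 2. These shares differed between the libraries of each group and were close in libraries of the same number. The list itself stood at 0.06 in Scr 1, -0.45 in Scr 2, 0.36 in miR-99 KD 1 and 0.16 in miR-99 KD 2. These are medians of log2 CPM minus the mean over libraries. The camera call was lost without Scr 2, at a median of 0.19 and an adjusted p of 0.140, and without miR-99 KD 1, at a median of 0.32 and an adjusted p of 0.0515. The median was 0.72 without Scr 1 and 0.63 without miR-99 KD 2. DESeq2 called 3 genes of the list without Scr 1 and 2 without Scr 2.

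Cell cycle lists rose by small amounts by camera. The DNA replication and G1/S list of 30 genes had a median log2 difference of 0.16 and an adjusted p of 0.017, with adjusted p = 0.732 with an estimated correlation. The mitosis list of 31 genes had a median of 0.17 and an adjusted p of 0.0041, with adjusted p = 0.732 with an estimated correlation. DESeq2 called 3 higher in the G1/S list, which were Ccne1, Ccne2 and Cdc45, and 2 in the mitosis list, which were Ube2c and Ccna2. Ccne1, a cyclin that drives entry into DNA synthesis, stood at 146 ± 4.9 CPM in Scr and 312 ± 67 in miR-99 KD. Ccna2, a cyclin of DNA synthesis and mitosis, stood at 403 ± 34 and 594 ± 83 CPM. Adjusted over the list alone, edgeR called 0 genes in either list. Without Scr 1 the G1/S list had a median of 0.09 and an adjusted p of 0.324, and mitosis a median of 0.06 and an adjusted p of 0.248. The G1/S median was 0.06 without miR-99 KD 2, at an adjusted p of 0.0943, and 0.25 without miR-99 KD 1. The mitosis call was also lost without miR-99 KD 1, at a median of 0.17 and an adjusted p of 0.0696.

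Lists of protein synthesis and respiration also rose by camera. The cytosolic ribosome list of 76 genes had a median log2 difference of 0.36 and an adjusted p of 5.7e-07, with adjusted p = 0.732 with an estimated correlation. In 21 of these genes both miR-99 KD libraries lay above both Scr libraries, in 1 below, and 54 overlapped, against 3750 above among all 15320 genes. The list stood at -0.05 in miR-99 KD 1 and 0.04 in Scr 1, as the median of log2 CPM minus the mean over libraries, and at 0.41 in miR-99 KD 2 and -0.37 in Scr 2. On the same scale the mitochondrial genome list stood at 0.12 in miR-99 KD 1, 0.40 in Scr 1, 0.48 in miR-99 KD 2 and -1.03 in Scr 2, where mitochondrial genes took 0.357% of gene counts. The ribosome biogenesis and MYC list of 28 genes had a median of 0.22 and an adjusted p of 7.5e-04, with adjusted p = 0.732 with an estimated correlation. The oxidative phosphorylation list of 42 genes had a median of 0.29 and an adjusted p of 1.8e-05, with adjusted p = 0.732 with an estimated correlation. Both miR-99 KD libraries lay above both Scr libraries in 32 of these genes. Srm, a polyamine synthesis enzyme, stood at 315 ± 9.8 CPM in Scr and 471 ± 3.7 in miR-99 KD, and Odc1, which acts in the same pathway, at 162 ± 1.8 and 223 ± 7.1. Rps10 stood at 36.3 ± 5.8 and 54.9 ± 13 CPM, and Sdha, a respiratory chain subunit, at 386 ± 88 and 264 ± 31 CPM. DESeq2 called Srm, Odc1 and Tfrc of the biogenesis list, and 0 genes of the ribosome and respiratory lists. Adjusted over the list alone, edgeR called 1 gene, Tfrc, in the biogenesis list and 0 in the others. Tfrc also belongs to the erythroid-megakaryocytic list, so its calls in the 2 lists are not separate. The ribosome median was 0.13 without Scr 2 and 0.55 without miR-99 KD 1. The ribosome call was lost without miR-99 KD 2, at a median of 0.13 and an adjusted p of 0.0562, and the biogenesis call without Scr 1, at a median of 0.15 and an adjusted p of 0.0844.

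Markers of cells outside the sort gate differed between the libraries within both groups. As the median of log2 CPM minus the mean over libraries, the B cell list stood at 0.16 in Scr 1, -1.83 in Scr 2, 1.96 in miR-99 KD 1 and -0.03 in miR-99 KD 2. The B cell list of 13 genes rose by camera, with a median log2 difference of 1.73 and an adjusted p of 0.0043, and an adjusted p of 0.732 with an estimated correlation. All 13 genes were highest in miR-99 KD 1, and without that library the median was 0.67 and the adjusted p 0.338. Without Scr 2 the median was 1.08 and the adjusted p 0.140, and without Scr 1 the median was 2.97. Vpreb1, part of the surrogate light chain of B cell precursors, stood at 2.92 ± 1.7 CPM in Scr and 19.3 ± 15 in miR-99 KD. Igll1, its partner, stood at 7.52 ± 3.1 and 38.4 ± 32 CPM, and DESeq2 called both. The neutrophil list of 16 genes did not pass, with a median of 1.53 and an adjusted p of 0.0546. All 16 were highest in miR-99 KD 1, and without it the median was -0.32. The same genes were higher in Scr 1 than in Scr 2 by a median of 1.19 on the log2 scale. Ngp, a neutrophil granule protein, stood at 10390 CPM in miR-99 KD 1, 1337 in miR-99 KD 2, 2048 in Scr 1 and 1078 in Scr 2.

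**Figure D2:**
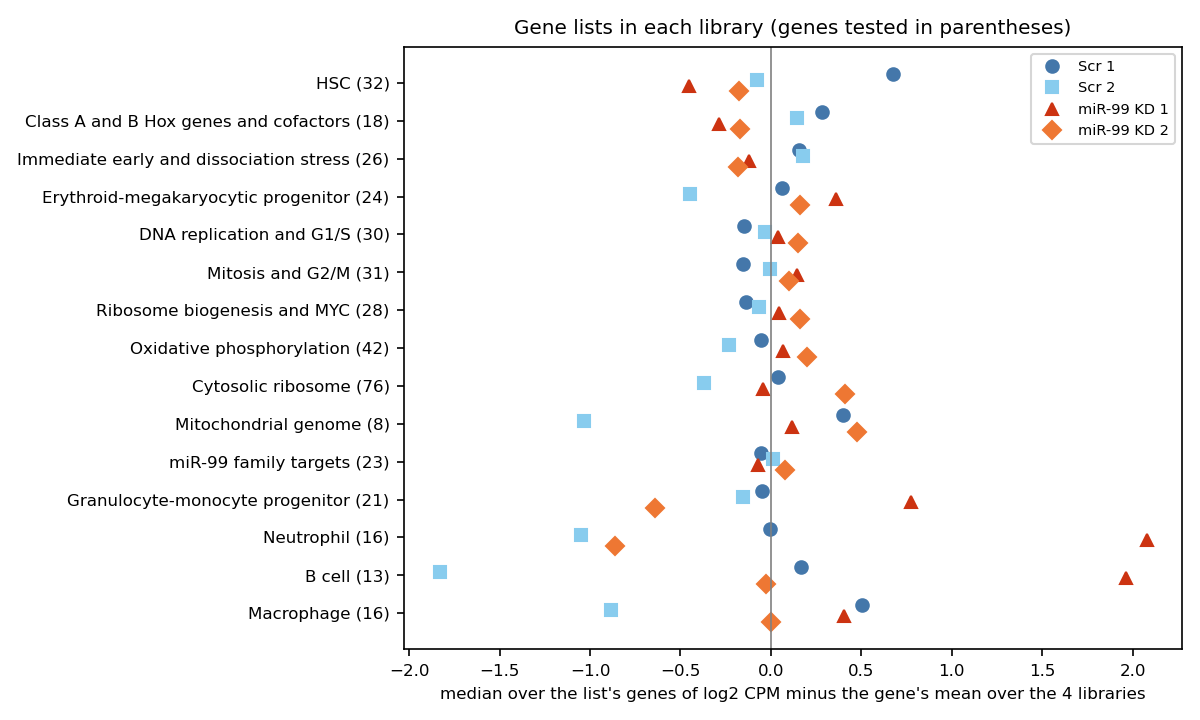
Median over each list's genes of the log2 CPM minus the gene's mean over the 4 libraries, with 1 symbol per library. The stem cell list stands at 0.67 in Scr 1, -0.08 in Scr 2, -0.45 in miR-99 KD 1 and -0.18 in miR-99 KD 2.

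The remaining lists did not pass camera. The miR-99 family targets, 23 genes, had a median log2 difference of 7.0e-04 and an adjusted p of 0.889. Mtor, a published target, stood at 39.3 ± 7.2 CPM in Scr and 39.3 ± 6.3 in miR-99 KD, and Rptor, its partner, at 53.3 ± 5.8 and 46.9 ± 8.1. Igf1r stood at 19.6 ± 1.2 and 20.9 ± 6.3 CPM and Smarca5 at 295 ± 16 and 377 ± 69. None of these 4 was called by edgeR or DESeq2. DESeq2 called 1 member, Smarcd1, lower at 77.4 ± 2.2 CPM in Scr and 52.8 ± 4.6 in miR-99 KD. At an unadjusted p under 0.05 edgeR counted 3 targets lower and 0 higher. Fzd5 and Raver2, the other lower ones, stood at 1.12 ± 0.065 and 9.05 ± 3.4 CPM in Scr and 0.283 ± 0.079 and 2.87 ± 2.1 in miR-99 KD. Adjusted over the list alone, edgeR called 0 targets.

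Other progenitor and blood cell lists gave camera adjusted p of 0.0896 for lymphoid-primed progenitors, 0.313 for granulocyte-monocyte progenitors, 0.164 for T and NK cells, 0.161 for macrophages, 0.0564 for mast cells and basophils, 0.889 for dendritic cells and 0.981 for endothelial and stromal cells. Single libraries moved some of their median log2 differences. The granulocyte-monocyte median turned from 0.93 without miR-99 KD 2 to -0.46 without miR-99 KD 1. The lymphoid-primed median was 0.71 without Scr 2 and -0.05 without miR-99 KD 1. The mast cell and basophil median was 3.03 without Scr 1 and 0.69 without miR-99 KD 1. In the lymphoid-primed list DESeq2 called Il7r and Ebf1 higher and Flt3 and Cd27 lower, and edgeR adjusted over the list alone called Cd27. Il7r and Ebf1 stood at 11.4 and 39.3 CPM in miR-99 KD 1, where the B cell list was highest, and at 2.67 and 12.2 in miR-99 KD 2. Without miR-99 KD 1 their log2 differences were 1.63 and 1.55 in place of 3.03 and 2.63. That of Flt3 was -0.60 without Scr 2 in place of -1.34. Cd27 stood at 86.1 ± 11 CPM in Scr and 46.4 ± 0.077 in miR-99 KD. Sparc and Plvap, of the endothelial and stromal list, were called higher by edgeR adjusted over the list alone. Sparc stood at 18.2 ± 7.3 and 47.5 ± 1.4 CPM. Emcn and Pdgfrb of the same list went the other way. Emcn stood at 6.08 ± 0.20 CPM in Scr and 1.51 ± 1.1 in miR-99 KD, and Pdgfrb at 33.1 ± 14 and 15.3 ± 3.5. At an unadjusted p under 0.05 edgeR counted 2 genes of this list higher and 2 lower.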

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

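The DESeq2 counts without each library and under the block, and the counts at an unadjusted p under the alternatives, were chosen after seeing the data. The cause of the changes given here was not tested. The count of genes called by edgeR, 0 over all 4 libraries, was 0 with limma-voom, glmTreat and every other scaling, 887 with DESeq2 and 1064 without a filter, and 0 to 1013 without each library in turn, the 1013 without miR-99 KD 1 and 437 without miR-99 KD 2. With 1 library left in a group, that library is assumed to vary like the other group. Genes at an unadjusted p under 0.05 numbered 1006 with glmTreat and 783 to 4342 without each library. DESeq2 called 27 to 1506 genes without each library; the 27 without Scr 2 shared 22 with the 887. It called 3 to 11 genes of the stem cell list and 2 to 9 of the erythroid list.

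The same-numbered libraries correlated at 0.057 in their deviations and there are 2 pairs, so the numbers were not taken to pair the mice. This does not exclude a batch or pairing by number. DESeq2 called 107 genes with the libraries split by number, and 10 in the other split that mixes the groups. With the replicate number as a block edgeR called 0 genes, DESeq2 390 and camera 14 lists. Camera called 8 lists in the main setting, 13 without a filter, 0 with an estimated correlation and 0 by fry, and 7 to 11 without each library. Of the lists called, oxidative phosphorylation alone passed in all 4 fits that left out a library, at adjusted p of 2.3e-05 to 0.0025. The median log2 difference was 0.02 over the 15320 genes kept by the filter. Without a filter it was -0.11 over 25446 genes, a larger set that takes in genes of low counts.

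Mtor, near 0, changed sign with DESeq2 (-0.0016), its size factors (-0.0017), upper-quartile factors (-0.027), library totals (-0.085), no filter (-0.026) and the 10 CPM filter (-0.027), and ran from -0.20 to 0.18 without each library. Without each library Ngp ran from -0.23 to 2.74, Cebpe from -0.16 to 2.69, Igsf6 from -0.14 to 2.20, Igf1r from -0.25 to 0.37 and Slc40a1 from -0.077 to 0.90. Lists that turned direction are given by camera adjusted p. Without a filter these were the miR-99 targets, dendritic cell and mTOR pathway lists (0.869 each), T and NK cell (0.852) and endothelial (0.917). With the 10 CPM filter they were the targets (0.626), endothelial (0.271) and sex-linked (0.742). Endothelial also turned with upper-quartile factors (0.967), library totals (0.852) and fry (0.981), and under the block dendritic cell (0.927) and mTOR pathway (0.956) did. Without each library the adjusted p ran from 0.498 to 0.890 for the targets, 5.4e-07 to 0.491 for granulocyte-monocyte, 0.016 to 0.866 for T and NK cell, 1.1e-06 to 0.626 for macrophage, 2.3e-08 to 0.338 for neutrophil, 0.191 to 0.978 for dendritic cell, 0.108 to 0.978 for endothelial, 0.525 to 0.754 for mTOR pathway, 1.1e-06 to 0.707 for mitochondrial genome and 0.137 to 0.975 for sex-linked. At a depth of 27295197 to 32350590 counts, 15320 of 45232 gene rows had enough counts to be tested.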

Other observations

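The immediate early and dissociation stress list, which did not pass camera at an adjusted p of 0.116, held single genes that moved. Adjusted over the list alone, edgeR called 6 lower and 2 higher of its 26 genes. Zfp36, which binds AU-rich messages, stood at 660 ± 30 CPM (SD, n = 2) in Scr and 336 ± 3.9 in miR-99 KD, and Nr4a1, an early response receptor, at 117 ± 37 and 41.7 ± 2.0 CPM. Egr1 stood at 394 ± 3.7 and 183 ± 54 CPM. Hsph1, a heat shock protein, stood the other way, at 137 ± 1.2 and 552 ± 305 CPM. The quiescence list of cell cycle inhibitors gave a camera adjusted p of 0.116. Over that list alone edgeR called 4 lower: Nr4a1, Egr1, Ccng2 and Cdkn1c. Nr4a1 and Egr1 also belong to the stress list, and Cdkn1c to the stem cell list. In the SWI/SNF and ISWI list, at an adjusted p of 0.489, Smarca2 and Arid1b were called lower over the list alone and Baz1a higher. Smarca2 stood at 135 ± 15 and 69.7 ± 4.2 CPM and Arid1b at 140 ± 4.5 and 71.0 ± 10.

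Hoxa9 and Meis1, 2 transcription factors of early progenitors, were called lower by DESeq2. Both also belong to the stem cell list. Meis1 stood at 228 ± 27 CPM in Scr and 84.2 ± 37 in miR-99 KD, and Hoxa9 at 72.5 ± 9.8 and 40.4 ± 1.4. Their list of Hox genes and cofactors gave a camera adjusted p of 0.138. The p53 response list gave 0.163, with Phlda3 at 5.55 ± 1.3 and 16.1 ± 0.90 CPM. The interferon list gave 0.180, with Ddx58 at 59.7 ± 0.042 and 30.8 ± 0.12 CPM. The G1 cyclin list and the list of mTORC1 and sterol synthesis gave 0.534 each, the insulin-like growth factor and mTOR list 0.994, the mitochondrial genome list 0.0896 and the sex-linked list 0.994.

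Of the tests that follow, those on length and GC and on the seed site were set before their results were seen, and the others after. The lists of the ribosome and the respiratory chain passed camera as higher, though not with an estimated correlation (adjusted p = 0.732 each) or by fry (adjusted p = 0.637 and 0.423), and their transcripts are short, with a median length of 1232 bases against 3118 for other genes. A trend of the log2 difference on transcript length and GC content, fitted on the other genes, moved the median of both lists together from 0.32 to 0.31, with a bootstrap 95% interval of 0.28 to 0.36 that treats genes as independent. The trend took up 2.20% of the variance of the other genes, and ran from -0.23 to 0.07 between their 10th and 90th percentiles. Lengths and GC contents were those of the longest annotated transcript of each gene, which may not be the one expressed. A trend on these annotated values did not account for the median of 0.31 in these 4 libraries. A bias from the length or GC of the expressed transcripts is not decided by it. The knockdown, and a difference in sample quality between libraries, stay open and untested.

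The stem cell list was lower and the erythroid list higher by camera, though not with an estimated correlation (adjusted p = 0.732 each) or by fry (adjusted p = 0.423 and 0.518). Neutrophils and B cells carried through the sort would dilute both lists, and the erythroid list had a median of 0.41. A rise of that list is part of the pattern itself, so this test is void. Without miR-99 KD 1 the neutrophil median was -0.32, the B cell median 0.67, the stem cell median -0.65 and the erythroid median 0.32, but this rests on 1 miR-99 KD library, and carried-over cells stay open. A larger share of erythroid progenitors also stays open, since the 10 early erythroid genes, whose log2 differences had a spread of 0.851 times a limit of 2 median standard errors, were picked after their values were seen, which makes that test void. A response of the stem cells to the knockdown is untested.

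The neutrophil list was higher in miR-99 KD on average. Without miR-99 KD 1 its median was -0.32 in place of 1.53, so a single library with more granulocytic RNA may account for it. All 16 genes were highest in that library, so leaving it out had to lower the median. The sort for lineage-negative cells would remove mature neutrophils. Ltf, an abundant granule protein chosen after its values were seen, stood at 5622 CPM in miR-99 KD 1 and 641 in miR-99 KD 2. The granulocyte-monocyte progenitor list stood at 0.77 and -0.64 in these 2 libraries, as the median of log2 CPM minus the mean over libraries. Whether mature neutrophils or granulocytic progenitors gave this RNA was not tested.

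Transcripts with a match to the miR-99 seed in the 3′ untranslated region were tested for higher levels in miR-99 KD. The 200 genes with the site TACGGGT, of 12857 searched, had a mean log2 difference of -0.03 ± 0.05 (SE over genes) after allowance for expression and length of the region. That lay at the 27.4th percentile of 179 shuffled sites. The bound set beforehand, a value at or below the shuffled median, was met, and a first reading took this as evidence against derepression. The value lies below that median by 0.022, less than its standard error, so the reading was changed, after the result was seen, to undecided. The 95% interval of the mean, which treats genes as independent, reached 0.068.

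With 2 libraries per group there are 3 splits, too few for a share under 0.05. DESeq2 called 887 genes in the real split, as many as in 1 of the 3 splits, itself. It called 107 with Scr 1 and miR-99 KD 1 set against Scr 2 and miR-99 KD 2, and 10 in the remaining split. Each of the other splits mixes the groups on both sides. A group difference would then add to the spread within sides and lower the calls, so 107 is no measure of chance. Camera called 8 lists in the real split and up to 10 in the others, so 3 of 3 splits gave as many. With Scr 1 and miR-99 KD 2 set against Scr 2 and miR-99 KD 1, the stem cell list was called at an adjusted p of 1.4e-04, the ribosome at 1.8e-16 and oxidative phosphorylation at 0.031. With Scr 1 and miR-99 KD 1 set against the other libraries, B cell was called at 3.1e-10 and erythroid at 1.1e-04. The stem cell, ribosome, B cell and erythroid values are smaller than those of the real split, which were 3.5e-04, 5.7e-07, 0.0043 and 0.0010. The G1/S, mitosis and ribosome biogenesis lists were called by camera in neither of the other splits, at adjusted p of 0.0586 or more. Since mixing the groups can lower these calls too, this does not set the 3 lists apart.

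The blank rows after the genes hold pasted library names and totals. In the library deposited as Scr 1 the total stands under the name Scr-2, in miR-99 KD 1 under Zip99a-2 and in miR-99 KD 2 under Zip99a-1. In Scr 2 the total of 28422748 stands under no name. A total of 29793890 pasted under the name Scr-1 equals the total of none of the 4 libraries.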
